A study of Mus musculus with 16 samples.

How the data were processed

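The series held 4 single-cell libraries of CD45-sorted mouse lung cells (sham, 2 libraries; mild pneumonia, 1; severe pneumonia, 1) and 12 bulk RNA libraries of sorted lung macrophages (unstimulated, NE, LPS, and NE then LPS, 3 each). Groups, doses and times were taken from the labels. The labels did not say whether the 3 libraries of a group came from separate mice, cultures or days.

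Bulk libraries were made from poly(A) RNA with a protocol that does not keep the strand, per the labels' protocols. Reads were trimmed with cutadapt, checked with FastQC, aligned to GRCm38 (mm10) with HISAT2 and assembled or quantified with StringTie, per the submitters' processing notes. Those notes gave no versions, no annotation and no account of how StringTie output became counts. The deposited bulk table held counts per gene for 57132 Ensembl identifiers. Low values in it were enriched at multiples of 4 (2.58 times their neighbours at 4 and 1.88 times at 8), a step the notes do not mention, so the deposited counts were read as about 4 per read pair. Libraries therefore held 14.9 to 19.0 M (mega) read pairs, and a gene with 3 read pairs over a whole group stood at 0.0575 (unstimulated), 0.0564 (NE), 0.0559 (LPS) or 0.0672 CPM (NE then LPS), the floors used for groups at 0. Gene symbols and coordinates came from GENCODE vM21 (GRCm38), which named 51880 identifiers (90.8%). The other 5252 carried 0.305% of the counts and stayed in the library totals and tests. Where 65 symbols were shared between identifiers, the identifiers were kept apart. The 100 highest genes held 32.9% to 35.64% of a library's counts and mitochondrial genes 3.292% to 4.139%.

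Single-cell matrices held UMI counts made with Cell Ranger, per the file headers (version 7.1.0) and per the submitters' processing notes (version 7.2.0). The deposited files for each library were a matrix of counts for 32285 genes with its barcodes and features, together with 1 annotation of cell classes for all libraries. The authors' annotation named 10 classes and no class called Mac2, so the Macrophage class was used as the nearest by name, although its sham cells carried mostly monocyte genes and do not match the sorted cells. It covered 5371 of 5841 barcodes in sham 1 (92.0%), 7556 of 8100 in sham 2 (93.3%), 10404 of 10963 in mild (94.9%) and 9935 of 10404 in severe (95.5%). Annotation suffixes 0, 1, 2 and 3 were assigned to sham 1, sham 2, severe and mild because 100% of each suffix's barcodes were present in that library and at most 0.484% in any other. Barcodes with no class were left out of shares and class values. No doublet caller was run and no barcode was removed as a doublet, and the submitters' processing notes name no such step, so class sums and subsets by UMI can hold doublets. The lowest UMI total of a barcode was 509, 501, 502 and 501 in sham 1, sham 2, mild and severe, and mitochondrial genes held 2.15%, 2.95%, 1.52% and 1.32% of UMIs.

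The tests, samples, alternatives and the rule for naming genes were written down before the data were examined. The bulk counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, group means only) on all 12 libraries, which kept 17217 genes. Benjamini-Hochberg adjustment was made within each comparison, and genes were called at an adjusted p under 0.05, two-sided. The comparisons were LPS with unstimulated, NE with unstimulated, NE then LPS with LPS, NE then LPS with NE, and the interaction of NE and LPS. The biological coefficient of variation was 13.1% (median over genes 10.7%), and counts of replicates varied 8.57 to 22.5 times as much as counting error alone. In deposited counts of which 4 stand for 1 read pair, part of that excess is the step itself. A regression coefficient is given as log2 fold change ± SE, and group levels as mean CPM ± SD. The SE was taken as the absolute log2 fold change divided by the square root of the test's F statistic. It is therefore approximate, and can be too small where a group lies near 0 counts. In comparisons of 3 with 3 libraries, a gene with no difference has a 10% chance that the groups do not overlap.

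Lists of genes were tested with limma 3.58.1 camera on voom values, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The 17 lists held 29 to 32 genes each and were written from general knowledge of the genes. They covered inflammatory cytokines and chemokines, interferon-stimulated genes, NF-kB feedback and target genes, cAMP and CREB targets, adrenergic receptors and cAMP signalling, anti-inflammatory genes, antigen presentation, interstitial macrophage identity, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis and LXR targets, oxidative stress and NRF2 targets, the unfolded protein and integrated stress responses, immediate-early and dissociation stress genes, cell cycle, phagocytosis, and inflammasome and pattern recognition genes. A further 18 lists of 10 markers each covered lung cell types, and 15 of these could be tested in bulk.

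Genes named in the text followed this rule. For each bulk comparison the candidates were (a) the 8 highest and 8 lowest log2 fold changes among called genes whose 3 libraries of 1 group all lay beyond the other group's 3 (not asked of the interaction) with a mean log2 CPM of at least 2, leaving out predicted or unnamed symbols. Added to these were (b) 21 genes always reported (Tnf, Il1b, Il6, Il10, Il12b, Cxcl1, Cxcl2, Cxcl10, Ccl2, Ccl3, Ifnb1, Nos2, Nr4a1, Nr4a3, Crem, Dusp1, Il1rn, Arg1, Mrc1, Adrb2 and Cx3cr1), and (c) up to 4 called members with the largest absolute change from each list. Of (a) and (c), the text gives those with a described function that carry the comparison. The gate genes Itgam, Ptprc, Adgre1, Fcgr1, Itgax, Ly6c2 and Ly6g were named because the sort used their proteins.

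Single-cell counts were summed per library and class in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Of the classes with at least 50 cells in every library, genes were named by rule in the Macrophage class and the 4 largest others (T cells, neutrophils, B cells and NK cells). Dendritic cells, monocytes and plasma cells also had at least 50 cells in every library. Shares had exact Clopper-Pearson 95% intervals and CPM exact Poisson 95% intervals. For each pneumonia library, the 5 highest and 5 lowest genes were taken among genes with at least 50 CPM in 1 of the libraries compared, at least a 2-fold difference from both sham libraries in the same direction, and a distance to the nearer sham library larger than that between the sham libraries (the size rule). The 21 genes above and Adrb1, S100a8, S100a9, Ly6g, Retnlg and Isg15 were always considered. List medians of log2 ratios to the shams, over members with at least 5 CPM and with 2 CPM added, were ranked among 10000 random lists. Macrophage-class sums were also tested with edgeR (12743 genes, biological coefficient of variation 19.5%).

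The methods were tested on simulated data. Of genes given a shift of 1 on the log2 scale in the bulk table, 45 of 50 raised and 40 of 50 lowered genes were called, as were 35 and 37 of 50 at a shift of 0.585, and 12 of 16176 unchanged genes were called. In simulated class sums, 192 of 200 genes shifted by 2 on the log2 scale and 7 unchanged genes among 12374 were called. Of 100 random lists with no shift, 1 fell in the outer 5% of the list ranking, and 20 of 20 shifted lists did.

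Alternatives for the bulk tests were RLE size factors, DESeq2 1.42.0, no low-count filter, a strict filter (at least 10 counts in every library of a group), TMM without the 500 highest genes, the replicate number as a block, only the 6 libraries compared, a log2 fold change of at least 1, and leaving out each of the 12 libraries. Counts divided by 4 were added after the data were seen. Lists were also tested with fry and with the block. Single-cell alternatives were cells with at least 1000 UMIs, shares without neutrophils, leaving out each sham library, a total without 7 neutrophil markers and mitochondrial genes, and RLE, DESeq2 and no filter for the class sums. Not used were the raw reads and the barcodes without a class, except for their marker sums. Figures were drawn with matplotlib 3.10.9.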

Results

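Lung immune cells of mice were measured in a pair of experiments. In the first, CD45-sorted lung cells of mice with sham treatment (2 libraries), mild pneumonia (1 library) or severe pneumonia (1 library) were profiled by droplet single-cell RNA sequencing. In the second, macrophages sorted from the lungs of wild-type mice were left unstimulated or were treated in culture. Their RNA was sequenced in bulk, with 3 libraries in each of 4 groups. The treatments were norepinephrine (NE, the main transmitter of sympathetic nerves; 10 µM for 3 hours), LPS (a bacterial cell-wall component sensed by TLR4; 10 ng/mL for 3 hours), or NE for 3 hours followed by LPS for 3 hours (NE then LPS). The sort gate, named Mac2 in the labels, required CD45, the macrophage proteins CD11b, CD64 and F4/80, and the receptors ADRB2 and CX3CR1. It excluded cells with Ly6C, Ly6G or CD11c. Total counts per bulk library, in M (mega-counts), were 69.3, 64.6 and 59.5 in unstimulated replicates 1, 2 and 3, and 62.1, 68.7 and 74.0 in the NE replicates. They were 74.8, 69.9 and 76.2 in the LPS replicates and 61.4, 63.3 and 70.5 in the NE then LPS replicates. Low counts piled up at multiples of 4, so these totals stood for about 14.9 to 19.0 M read pairs per library. The single-cell libraries held 5841 (sham 1), 8100 (sham 2), 10963 (mild) and 10404 (severe) barcodes, with 47.8, 72.5, 88.2 and 78.8 M UMIs. Median UMIs per barcode were 6298, 6662, 5771 and 5282.5 in the same order.

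Transcripts of the gate's antigens were measured first in the unstimulated sorted macrophages. Itgam (CD11b) stood at 2870 ± 30.6 CPM (library-size-scaled counts, mean ± SD, n = 3 here and in every bulk group), Ptprc (CD45) at 480 ± 7.36, Adgre1 (F4/80) at 400 ± 11.1, Fcgr1 (CD64) at 46.6 ± 1.19 and Adrb2 (the beta-2 adrenergic receptor) at 18.7 ± 1.29 CPM. Itgax, which encodes the CD11c that the gate excluded, stood at 1870 ± 28.1 CPM, and Ly6c2 at 38.7 ± 1.79 CPM. Cx3cr1, whose protein the gate required, was at 0.381 ± 0.134 CPM, and Ly6g was at 0.0192 ± 0.0332 CPM. In the annotated Macrophage class of the single-cell data the order was the other way round, with Cx3cr1 at 97.1 and 140 CPM and Itgax at 11.2 and 7.26 CPM in sham 1 and sham 2. That class is not matched to the sorted cells, since 93.0% and 95.5% of its sham cells carried a Ly6c2 or Ccr2 UMI and no C1q UMI. None of the lists of markers for other cell types passed the list test in any bulk comparison (smallest adjusted p = 0.0512, limma camera). By contrast, fry, which asks whether a list changed at all, called many. It called most of them in LPS or NE against unstimulated and in NE then LPS against NE. Both tests compare the treatment groups, so neither measures the purity of the sort. On the main axes of variation among the bulk libraries, the first component (33.6% of the variance) separated the 6 libraries with LPS from the 6 without, and the second (17.4%) separated the 6 with NE from the 6 without.

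The comparison of LPS with unstimulated libraries asked what differed after LPS alone in these macrophages. The labels do not say how long the unstimulated cells were cultured, so LPS and time in culture are not separated here. LPS raised the neutrophil chemokine Cxcl1 3070-fold (log2 11.58 ± 0.10 SE, 0.0743 to 241 CPM, adjusted p = 4.21e-20), the cytokine Il6 541-fold (9.08 ± 0.12, 0.389 to 213 CPM) and Il1b 182-fold (7.51 ± 0.08, 12.7 to 2310 CPM). The unstimulated Cxcl1 level lies near the floor of 3 read pairs (0.0575 CPM), so the size of its fold is less certain than its SE shows. Tnf rose 53.8-fold (5.75 ± 0.05, 40.5 ± 1.44 to 2180 ± 25.1 CPM, adjusted p = 3.46e-20). Ptgs2, the inducible enzyme of prostaglandin synthesis, rose from 2.42 to 1230 CPM (9 on the log2 scale), and Nos2, the inducible nitric oxide synthase, rose 120-fold (6.90 ± 0.21). Il10, which encodes an anti-inflammatory cytokine, had no counts in the unstimulated libraries and 0.402 ± 0.138 CPM after LPS, at least 6.99-fold higher (adjusted p = 2.64e-06). The beta-2 receptor gene Adrb2 fell from 18.7 to 5.35 CPM, 3.49-fold lower (log2 -1.80 ± 0.08, adjusted p = 4.03e-11). These genes lie on GRCm38 at 5:90891241-90893115 (Cxcl1), 5:30013114-30019981 (Il6), 2:129364570-129371139 (Il1b), 17:35199381-35202007 (Tnf), 1:131019845-131024974 (Il10) and 18:62177816-62179959 (Adrb2).

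Inflammatory genes rose almost as a whole after LPS. Of 31 measured cytokine and chemokine genes, 30 rose and 0 fell (30 and 0 adjusted over the list alone, median log2 5.12, camera adjusted p = 1.12e-30). Il23a was at 14.1 ± 0.38 CPM after LPS and at 0 before (at least 246-fold higher), and Il12a and Csf3 were at least 124-fold and at least 84-fold higher. Cxcl2 rose 259-fold, Il12b 236-fold, Ccl3 8.56-fold and Ccl2 1.95-fold. Ifnb1, the gene of interferon beta, rose to 2.16 CPM from 2 counts over the unstimulated libraries (adjusted p = 3.48e-07), a level under the floor of 3 read pairs, so no fold is given. All 30 NF-kB feedback and target genes rose (30 adjusted over the list alone, median log2 2, adjusted p = 1.77e-43). Among them were Nfkbiz (67.8-fold), the co-stimulatory receptor Cd40 (25.6-fold) and the inhibitor Tnfaip3 (8.76-fold). Interferon-stimulated genes rose in 31 of 32 (31 adjusted over the list alone, median log2 2.41, adjusted p = 2.41e-28), with Cxcl10 up 294-fold and Ifit1 up 33.5-fold. All 3 list calls held with an estimated correlation (adjusted p = 0.00466 for cytokines, 0.000569 for NF-kB and 0.0195 for interferon-stimulated genes).

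Antigen presentation genes rose in 22 of 30 and fell in 2 (24 and 2 adjusted over the list alone, adjusted p = 7.18e-09, and 0.00963 with an estimated correlation). The co-stimulatory gene Cd80 rose 1.98-fold and the peptide transporter Tap1 1.74-fold. Oxidative stress and NRF2 target genes rose in 17 of 30 and fell in 2 (18 and 2 adjusted over the list alone, adjusted p = 4.47e-07, and 0.0448 with an estimated correlation). Sqstm1 rose 2.99-fold and the cystine carrier Slc7a11 2.91-fold. Inflammasome and pattern recognition genes rose in 16 and fell in 6 of 30 (16 and 6 adjusted over the list alone, adjusted p = 0.000146, and 0.00963 with an estimated correlation). Nlrp3 rose 7.49-fold and Tlr2 6.01-fold. Immediate-early and dissociation stress genes rose in 17 and fell in 9 of 29 (17 and 9 adjusted over the list alone, adjusted p = 0.003, and 0.0195 with an estimated correlation). Among these, the feedback genes Nfkbia (6.62-fold) and Socs3 (5.04-fold) rose while Fos fell from 36.7 to 8.15 CPM. Cell cycle genes fell in 20 and rose in 2 of 30 (23 and 2 adjusted over the list alone, median log2 -0.27, adjusted p = 0.000116, and 0.031 with an estimated correlation). Ccnd1 was 1.86-fold lower, whereas Mki67 ran against its list and rose 3.86-fold (63.2 ± 3.01 to 244 ± 4.52 CPM).

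The cAMP and CREB target genes were called higher with the preset correlation (15 rose and 9 fell of 29; 16 and 9 adjusted over the list alone, adjusted p = 0.0323), but not with the other setting (adjusted p = 0.37 with an estimated correlation). The same held for unfolded protein and integrated stress response genes (14 rose and 4 fell of 30; 14 and 5 adjusted over the list alone, adjusted p = 0.0103, and 0.28 with an estimated correlation). Adrenergic receptor and cAMP signalling genes did not pass (5 rose and 13 fell of 26; 7 and 14 adjusted over the list alone, adjusted p = 0.05), although Adrb1 was 5.63-fold lower (-2.49 ± 0.41). No call was made for anti-inflammatory (adjusted p = 0.871), interstitial macrophage identity (0.529), glycolysis and hypoxia (0.529), oxidative phosphorylation (0.149), cholesterol and LXR (0.183) or phagocytosis genes (0.343), and the members of each went both ways. For anti-inflammatory and glycolysis genes the median log2 change was negative (-0.07 and -0.04) while the mean was positive (0.17 and 0.34), and for phagocytosis genes the median was -0.02 and the mean 0.10. The itaconate enzyme Acod1 nevertheless rose 14.7-fold (263 to 3870 CPM), the oxysterol enzyme Ch25h rose 7.37-fold and the cholesterol exporter Abcg1 was 2.66-fold lower. The macrophage transcription factors Klf4 and Mafb were 7.2-fold and 6.23-fold lower (-2.85 ± 0.09 and -2.64 ± 0.09). Il1rn, the interleukin-1 receptor antagonist, rose 1.48-fold, Nr4a3 2.81-fold and Dusp1 by 0.28 ± 0.07 on the log2 scale. Nr4a1 (0.07, adjusted p = 0.788), Arg1 (-0.07; 0.872), Mrc1 (-0.07; 0.0819) and Cx3cr1 (-0.20; 0.897) were not called.

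Of 17217 genes tested with edgeR, 3293 were higher and 3055 lower after LPS at a Benjamini-Hochberg adjusted p under 0.05 (36.9%), and 908 and 503 of them differed by at least 2-fold. Crem was called lower by a small amount (-0.23 ± 0.07, adjusted p = 0.0134), a call that was lost without unstimulated replicate 2 or 3, without LPS replicate 2 or 3, and with only the 6 libraries compared (adjusted p = 0.0519 to 0.0725). The p-values here and below measure only the spread between these libraries, since the labels do not say whether libraries of a group came from separate mice, separate cultures or separate days.

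**Figure D1:**
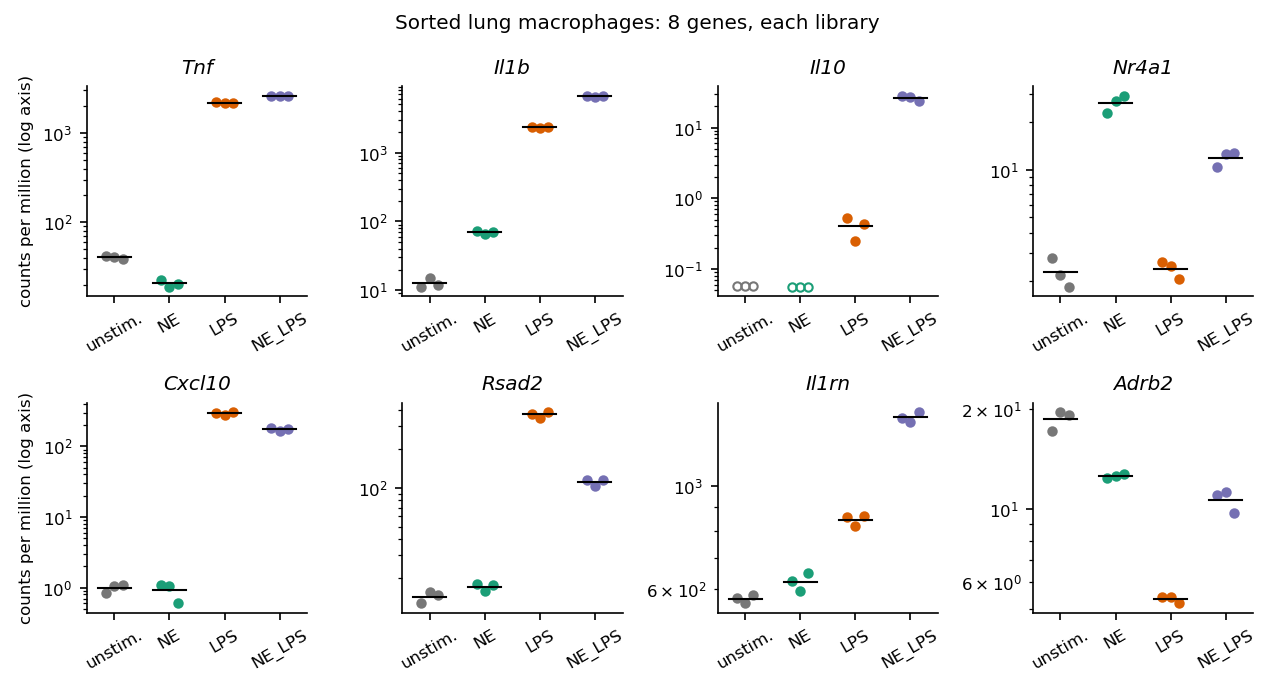
CPM (log axis) of 8 genes in the 12 bulk libraries, by group; points are libraries, black lines are group means, and open symbols mark libraries with 0 counts, drawn at the group's floor. Il10 reached 26.3 CPM only in the NE then LPS group, and Adrb2 was lowest after LPS alone, at 5.35 CPM.

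The comparison of NE with unstimulated libraries asked what differed after the transmitter without LPS. It has the same limit, as the time in culture of the unstimulated cells is not given. NE raised Thbs1, the gene of the matrix protein thrombospondin-1, 102-fold (log2 6.68 ± 0.05, 44.9 ± 1.20 to 4590 ± 245 CPM, adjusted p = 7.1e-21). The growth factor gene Vegfa rose 20.6-fold (4.37 ± 0.11), the lipid droplet gene Hilpda 23.1-fold, and the cAMP-responsive transcription factors Crem, Fosb and Nr4a1 19.7-fold (4.30 ± 0.07), 41.2-fold (5.37 ± 0.22) and 11.5-fold (3.52 ± 0.15). Cd14, the LPS co-receptor, rose 14.7-fold (3.88 ± 0.04, 81.1 ± 5.43 to 1190 ± 25.3 CPM). Tnf fell from 40.5 to 20.5 CPM, 1.98-fold lower (-0.98 ± 0.04, adjusted p = 5.99e-11), while Il1b rose 5.57-fold (2.48 ± 0.07, adjusted p = 1.68e-13). Thbs1 lies on GRCm38 at 2:118111876-118127133, Vegfa at 17:46016993-46032369, Crem at 18:3266048-3337748, Nr4a1 at 15:101254269-101274795 and Cd14 at 18:36725067-36726798.

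The cAMP and CREB target list rose as a group, with 23 of 29 members higher and 4 lower (23 and 4 adjusted over the list alone, median log2 1.66, camera adjusted p = 2.16e-16, and 0.0222 with an estimated correlation). Its members included Nr4a2 (17.3-fold), the feedback phosphatase Dusp1 (3.64-fold) and Nr4a3 (1.66-fold). It was the sole list of the 17 whose call held in this comparison with an estimated correlation. Genes of cholesterol synthesis and LXR targets fell in 22 and rose in 3 of 28 (23 and 3 adjusted over the list alone, median log2 -0.31, adjusted p = 5.42e-07, and 0.077 with an estimated correlation). Within that list the exporter Abca1 rose 4.43-fold (74.4 to 329 CPM) while Abcg1 was 1.67-fold lower and Ch25h 2.92-fold lower. Interferon-stimulated genes fell in 13 and rose in 3 of 32 (17 and 4 adjusted over the list alone, median log2 -0.20, or -0.17 with members at 0 counts set to their bound, adjusted p = 0.0113, and 0.556 with an estimated correlation). Ifit3 was 1.99-fold lower and Mx2 2.07-fold lower, both from levels under 5 CPM. Oxidative phosphorylation genes rose in 12 of 30 (14 adjusted over the list alone) by small amounts (median log2 0.09, adjusted p = 0.0048, and 0.257 with an estimated correlation).

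Glycolysis and hypoxia genes rose in 11 and fell in 4 of 30 (12 and 4 adjusted over the list alone, adjusted p = 0.0168), and cell cycle genes fell in 8 and rose in 3 of 30 (8 and 3 adjusted over the list alone, adjusted p = 0.0243). Each of these calls had adjusted p = 0.257 with an estimated correlation. The lactate carrier Slc16a3 rose 2.34-fold and Ndrg1 1.9-fold, whereas Acod1 was 2.16-fold lower. Cytokine and chemokine genes split, with 15 higher and 8 lower of 31 (16 and 10 adjusted over the list alone, adjusted p = 0.168). Ptgs2 rose 8.02-fold, Cxcl1 6.01-fold (2.59 ± 0.28) and Cxcl2 3.65-fold, while Ccl2 was 2.55-fold lower (-1.35 ± 0.04, 230 to 90.0 CPM) and Ccl3 2.17-fold lower (-1.12 ± 0.04). NF-kB genes (13 higher and 9 lower of 30, or 14 and 10 adjusted over the list alone, adjusted p = 0.0785), antigen presentation genes (12 and 5 of 30, or 13 and 7; 0.0545), NRF2 targets (12 and 7 of 30, or 13 and 9; 0.118) and stress response genes (10 and 5 of 30, or 12 and 5; 0.0785) were not called as groups. The co-stimulatory genes Cd80 and Cd86 rose 3.77-fold and 2.15-fold, Cd83 rose 4-fold, Icam1 was 2.29-fold lower, and Hmox1, the heme-degrading enzyme, was 1.92-fold lower. Nlrp3 rose 3.47-fold although its list was not called (8 higher and 15 lower of 30, median log2 -0.15, mean 0.17; 0.513).

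No group call was made for adrenergic signalling (adjusted p = 0.906), anti-inflammatory (0.749), interstitial macrophage identity (0.749), immediate-early (0.536, median log2 -0.10, mean 0.11) or phagocytosis genes (0.423). The decoy receptor Il1r2 rose 3.83-fold and Arg1 3.4-fold (1.77 ± 0.26), Mrc1 rose 1.11-fold, and both beta receptor genes were lower, Adrb2 by 1.49-fold (-0.57 ± 0.08) and Adrb1 by 2.88-fold (-1.53 ± 0.39). Adrb1 lost its call without unstimulated replicate 2 (adjusted p = 0.0508). Il10 stayed at 0 counts in all 6 libraries, and Cxcl10 (-0.14, adjusted p = 0.674) and Ifnb1 (adjusted p = 0.219) were not called. The genes that fell most by rule were Npas4 (7.45-fold lower), the potassium channel gene Kcnj2 (5.33-fold lower), Cited4 (4.14-fold lower) and F3, the tissue factor gene (4.05-fold lower). In total 2343 genes were higher and 2570 lower after NE (28.5% of those tested), and 487 and 243 of them by at least 2-fold. Small changes in Il6 (1.12 ± 0.24), Il12b (-0.82 ± 0.17) and Nos2 (1.23 ± 0.28) were called in the fit to all 12 libraries but not with only the 6 libraries compared (adjusted p = 0.0599, 0.0585 and 0.0511). Il1rn (0.12 ± 0.03) lost its call without unstimulated replicate 2 or NE replicate 3 (0.0504 and 0.0527), and Cx3cr1 (from 0.381 CPM to 0.0359, under the floor) without unstimulated replicate 1 or NE replicate 2 or 3 (0.07 to 0.0714).

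The comparison of NE then LPS with LPS alone addressed the question of the series most directly, namely how NE given first altered the cells' state after LPS. Pretreated cells had more Il10 mRNA, 26.3 ± 2.28 against 0.402 ± 0.138 CPM, or 64.7-fold (log2 6.02 ± 0.21, adjusted p = 7.46e-10). They also had more Il1b (2.86-fold, 1.51 ± 0.06, 2310 ± 44.7 to 6610 ± 113 CPM), Il6 (3.3-fold, 1.72 ± 0.07), Cxcl1 (3.5-fold, 1.81 ± 0.05) and Il23a (10.8-fold). Tnf differed little, at 2180 ± 25.1 and 2610 ± 27.5 CPM (1.19-fold higher; 0.26 ± 0.04, adjusted p = 9.48e-05). Lower with pretreatment were Ccl3 (2.7-fold lower, -1.43 ± 0.04), Ccl2 (2.3-fold lower, -1.20 ± 0.04), Cxcl10 (1.67-fold lower, -0.74 ± 0.07) and Il12b (1.57-fold lower, -0.65 ± 0.06). Adrb2 was 1.99-fold higher (0.99 ± 0.08), still below the unstimulated level.

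Interferon-stimulated genes fell together, with 31 of 32 lower and 0 higher (31 and 0 adjusted over the list alone, median log2 -0.83, camera adjusted p = 1.19e-28, and 0.0314 with an estimated correlation). Ifit2 was 6.04-fold lower (-2.60 ± 0.36, 167 to 27.6 CPM), Ifit3 5.69-fold lower (-2.51 ± 0.12, 48.9 to 8.61 CPM) and the nucleotide kinase gene Cmpk2 3.91-fold lower (-1.97 ± 0.12, 127 to 32.6 CPM). Ifnb1 itself was 2.7-fold lower (-1.43 ± 0.40, 2.16 to 0.8 CPM, adjusted p = 0.0151), a call lost without LPS replicate 1 or 3 or NE then LPS replicate 2 or 3 (adjusted p = 0.053 to 0.0636). In NE without LPS the same list was lower by a median of -0.20, a call not held with an estimated correlation, as given above. NF-kB genes rose in 22 and fell in 5 of 30 (22 and 6 adjusted over the list alone, median log2 0.40, adjusted p = 8.69e-12, and 0.0271 with an estimated correlation). Nfkbiz rose 2.12-fold and the inhibitor Nfkbia 1.86-fold, and Zc3h12c was 2.77-fold lower. The cAMP and CREB targets rose in 24 and fell in 4 of 29 (24 and 4 adjusted over the list alone, median log2 1.34, adjusted p = 1.91e-17, and 0.0262 with an estimated correlation). Thbs1 rose 21.5-fold (4.42 ± 0.04), Crem 16.9-fold (4.08 ± 0.07), Vegfa 16.3-fold (4.03 ± 0.11), Areg, an EGF receptor ligand, 18.2-fold, Nr4a1 4.97-fold and Dusp1 4.4-fold.

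Cytokine and chemokine genes rose in 17 and fell in 7 of 31 (18 and 7 adjusted over the list alone, adjusted p = 0.000153, and 0.212 with an estimated correlation). The granulocyte growth factor Csf3 rose 28.5-fold (4.83 to 138 CPM), Lif 5.04-fold, Osm 4.8-fold and Cxcl2 1.74-fold. Cholesterol and LXR genes fell in 13 and rose in 5 of 28 (13 and 5 adjusted over the list alone, adjusted p = 0.00632), and glycolysis and hypoxia genes rose in 11 and fell in 3 of 30 (11 and 3 adjusted over the list alone, adjusted p = 0.00798). Neither was called with the other setting (adjusted p = 0.212 for both with an estimated correlation). Within them, Abca1 rose 3.22-fold, and hexokinase Hk2 and Slc16a3 rose 2.07-fold and 2.58-fold. Immediate-early genes rose in 12 and fell in 8 of 29 (13 and 9 adjusted over the list alone, adjusted p = 0.0195, and 0.0727 with an estimated correlation). Of these, Ier3 rose 5.17-fold and Atf3 was 2.61-fold lower. Not called were adrenergic signalling (adjusted p = 0.132), anti-inflammatory (0.208), antigen presentation (0.89), identity (0.624), oxidative phosphorylation (0.336), NRF2 (0.289), stress response (0.243), cell cycle (0.15), phagocytosis (0.336) and inflammasome genes (0.677, median log2 -0.13, mean 0.03). Cd14 rose 7.09-fold, from 380 to 2700 CPM, Nlrp3 3.1-fold, Mafb 2.58-fold and Il1rn 1.66-fold (0.73 ± 0.03, 847 to 1400 CPM), and Hmox1 was 1.87-fold lower. Nos2 (-0.17, adjusted p = 0.407), Arg1 (0.69; 0.0642) and Cx3cr1 (0.402) were not called. Mrc1 rose by 0.18 ± 0.03 and Nr4a3 by 0.74 on the log2 scale. By edgeR, 2531 genes were higher and 2456 lower (29%), 514 and 271 of them by at least 2-fold. By the labels, pretreated cells had 6 hours with stimuli and cells given LPS alone 3. The labels do not say how long the latter were cultured before LPS, so NE and time in culture are not separated.

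**Figure D2:**
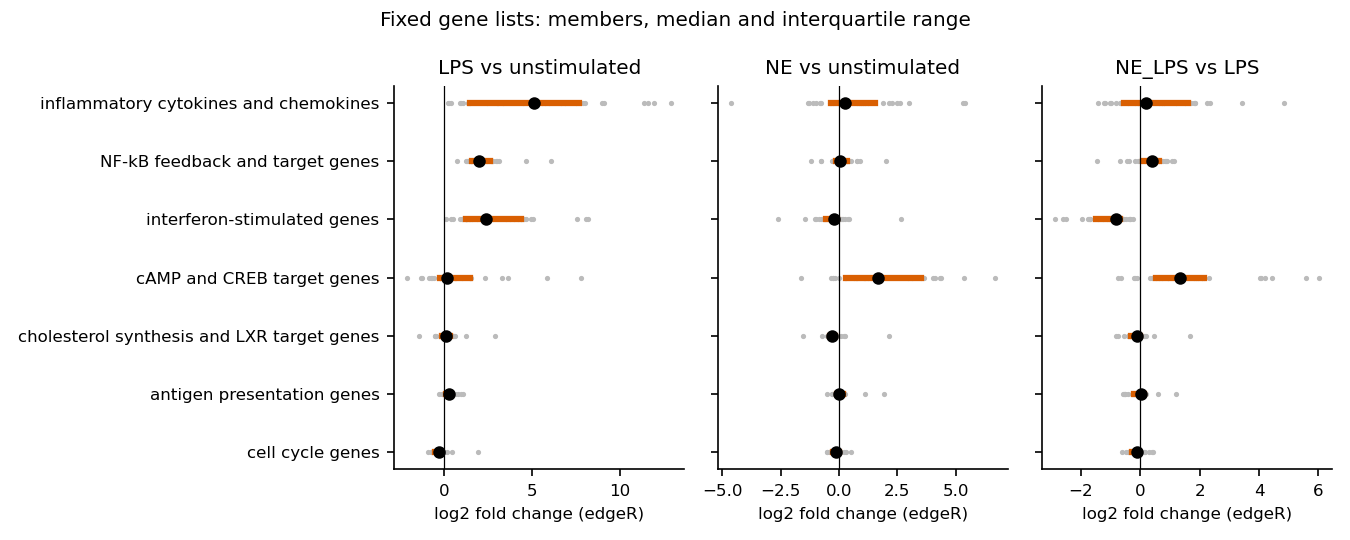
Log2 fold changes of the members of 7 gene lists in 3 bulk comparisons; grey points are genes, bars span the interquartile range and black marks are medians. Interferon-stimulated genes had a median of 2.41 after LPS and of -0.83 in NE then LPS against LPS, while the cAMP and CREB targets had medians of 1.66 after NE and 1.34 in NE then LPS against LPS.

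The comparison of NE then LPS with NE alone asked how pretreated cells changed over the 3 hours with LPS. By the labels it carries those further hours after NE along with LPS, so a waning of brief NE effects is not separated from the LPS response. Cxcl1 rose 1790-fold (10.81 ± 0.08), Il6 823-fold (9.69 ± 0.11), Ptgs2 227-fold, Il1a 173-fold, Tnf 127-fold (6.99 ± 0.05, 20.5 to 2610 CPM) and Il1b 93.7-fold (6.55 ± 0.08). Il10 went from 0 counts to 26.3 CPM, at least 466-fold higher (adjusted p = 5.74e-11), and Il23a was at least 2720-fold higher. Cxcl10 rose 193-fold, Il12b 264-fold, Cxcl2 124-fold, Ccl3 6.87-fold, Ccl2 2.16-fold and Nos2 45.5-fold. The anticoagulant receptor gene Thbd (9.65-fold lower, -3.27 ± 0.16), the G-protein regulator Rgs2 (7.7-fold lower), the adenosine-forming enzyme Nt5e (7.24-fold lower) and Fos (6.57-fold lower) had the largest falls by rule.

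Cytokine genes rose in 30 and fell in 0 of 31 (30 and 0 adjusted over the list alone, median log2 4.43, camera adjusted p = 8.23e-32, and 0.00408 with an estimated correlation). NF-kB genes rose in 30 of 30 (30 adjusted over the list alone, median log2 2.26, adjusted p = 2.56e-43, and 0.000577 with an estimated correlation). Interferon-stimulated genes rose in 30 and fell in 1 of 32 (30 and 1 adjusted over the list alone, median log2 1.60, adjusted p = 1.25e-16, and 0.0564 with an estimated correlation). Inflammasome genes rose in 13 and fell in 6 of 30 (13 and 6 adjusted over the list alone, adjusted p = 0.000979, and 0.0173 with an estimated correlation). Immediate-early genes rose in 18 and fell in 7 of 29 (18 and 7 adjusted over the list alone, 0.000236, and 0.0121 with an estimated correlation). Antigen presentation genes rose in 15 and fell in 1 of 30 (16 and 1 adjusted over the list alone, adjusted p = 0.000181, and 0.0564 with an estimated correlation). NRF2 targets rose in 17 and fell in 2 of 30 (18 and 2 adjusted over the list alone, 6.49e-06, and 0.0648 with an estimated correlation). Cholesterol and LXR genes rose in 17 and fell in 5 of 28 (17 and 5 adjusted over the list alone, 0.00432, and 0.174 with an estimated correlation). Cell cycle genes fell in 16 and rose in 3 of 30 (19 and 3 adjusted over the list alone, 0.000823, and 0.0564 with an estimated correlation), again with Mki67 rising (5.57-fold). Sqstm1 rose 3.24-fold, Ch25h 12-fold and Acod1 31.8-fold.

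The other lists were not called: cAMP and CREB targets (13 higher and 13 lower of 29, adjusted p = 0.739), adrenergic signalling (0.344), anti-inflammatory (0.932, median log2 -0.07, mean 0.43), identity (0.733), glycolysis (0.721, median -0.05, mean 0.54), oxidative phosphorylation (0.733), stress response (0.127) and phagocytosis genes (0.733). Crem was lower by -0.45 ± 0.06 and Nr4a1 2.21-fold lower, whereas Nr4a3 rose 2.83-fold and Dusp1 by 0.56 on the log2 scale. Il1rn rose 2.25-fold, Arg1 was 2.22-fold lower, and Mrc1 (-0.04, adjusted p = 0.319) and Cx3cr1 (0.143) were not called. Ifnb1 went from 0 counts to 0.8 CPM, at least 14.2-fold higher. Adrb2 was called slightly lower (-0.24 ± 0.08; 0.0272), a call lost without NE replicate 2 or 3, without NE then LPS replicate 3, and with only the 6 libraries compared (0.0525 to 0.136). In all, 3532 genes were higher and 3211 lower (39.2%), 986 and 588 of them by at least 2-fold.

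The interaction tested whether the LPS response itself differed between cells given NE first and cells given LPS alone, with the same limit of time. A positive value marks a larger rise, a smaller fall or a turn from fall to rise after NE, and a negative value the reverse. The LPS response of interferon-stimulated genes was weaker after NE, with a negative interaction in 23 of 32 members and a positive one in 0 (28 and 0 adjusted over the list alone, median log2 -0.72, camera adjusted p = 6.12e-26, and 0.0303 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, stood at 14.3, 17.1, 368 and 110 CPM in unstimulated, NE, LPS and NE then LPS libraries (interaction -2 ± 0.10 on the log2 scale; GRCm38 12:26442746-26456452). The Tnf response was larger after NE by 1.24 ± 0.06 (adjusted p = 1.95e-09), from a lower starting level, and the Il1b response was smaller by -0.96 ± 0.09 (3.63e-06), from a higher one. NF-kB genes had a positive interaction in 15 and a negative one in 3 of 30 (18 and 3 adjusted over the list alone, median log2 0.24, adjusted p = 3.46e-10). Immediate-early genes had a positive one in 9 and a negative one in 4 of 29 (10 and 5 adjusted over the list alone, 0.000448). Antigen presentation genes had a negative one in 7 and a positive one in 0 of 30 (10 and 1 adjusted over the list alone, 2.07e-06). Each of these 3 list calls had adjusted p = 0.0303 with an estimated correlation.

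Odc1, the rate-limiting enzyme of polyamine synthesis, stood at 84.2, 179, 74.9 and 479 CPM in the same order of groups (1.59 ± 0.05), and Lif, an IL-6 family cytokine, at 2.89, 2.38, 29.1 and 147 CPM (2.61 ± 0.13). Adrb2 had an interaction of 1.56 ± 0.12, as LPS lowered it less in pretreated cells. The phosphodiesterase Pde4b, which degrades cAMP, stood at 6.36, 78.4, 78.6 and 275 CPM (-1.81 ± 0.07). Cxcl2 (-1.07 ± 0.12), Nos2 (-1.40 ± 0.31) and Ccl3 (-0.32 ± 0.06) rose less with LPS after NE, and Il1rn rose more (0.61 ± 0.05). Nr4a1 (-1.21 ± 0.20) was not changed by LPS alone and fell in pretreated cells. No interaction was called for Il6 (0.61 ± 0.26, adjusted p = 0.237), Cxcl1 (-0.78; 0.203), Cxcl10 (-0.61; 0.092), Il12b (0.16; 0.747), Ccl2 (0.15; 0.131), Crem (-0.22; 0.178), Dusp1 (0.27; 0.115), Nr4a3 (0.01; 0.983), Mrc1 (0.835), Arg1 (0.114), Ifnb1 (0.65) or Cx3cr1 (0.448). Il10 was at 0 counts in both groups without LPS, so its interaction has no interpretable size. Cholesterol and LXR genes (7 positive and 1 negative of 28, or 9 and 1 adjusted over the list alone, 0.000659), cAMP and CREB targets (4 and 10 of 29, or 5 and 11 adjusted over the list alone, median log2 0, mean -0.13; 0.00601) and oxidative phosphorylation genes (0 and 0 of 30, also adjusted over the list alone, 0.00601) were called with the preset correlation but not with the other setting (adjusted p = 0.159, 0.288 and 0.202 with an estimated correlation). The remaining lists were not called: cytokines (0.526), adrenergic signalling (0.224), anti-inflammatory (0.298), identity (0.285), glycolysis (0.224), NRF2 (0.224), stress response (0.357), cell cycle (0.654), phagocytosis (0.846) and inflammasome genes (0.526). In total 620 genes had a positive and 506 a negative interaction (6.5% of those tested), 71 and 78 of them by at least 2-fold.

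The NE effects without and with LPS, which share no library, were compared gene by gene. Of the genes tested, 1637 were called higher in both (344 if calls fell independently) and 1656 lower in both (367 if independent), while 96 were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.413 and Spearman's rho = 0.486. For the LPS effects without and with NE, 2668 genes were called higher in both (676 if independent), 2227 lower in both (570 if independent) and 66 in opposite directions, with r = 0.638 and rho = 0.637 across genes.

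The single-cell libraries addressed which lung immune cells and genes differed with mild and severe pneumonia, by the authors' 10 cell classes. Neutrophils made up 6.05% (95% interval 5.43 to 6.72) and 4.41% (3.96 to 4.89) of annotated cells in the sham libraries, 41.6% (40.7 to 42.6) in mild and 52.7% (51.7 to 53.7) in severe pneumonia, 7.96 and 10.1 times the sham mean. The Macrophage class held 1.86% and 3.49% of sham cells, 9.16% (8.61 to 9.73) of mild and 10.2% (9.66 to 10.9) of severe cells, 3.42 and 3.83 times the sham mean. T cells made up 43.3% and 53.4% of sham cells against 27.8% in mild and 15.3% in severe pneumonia, 1.74-fold and 3.17-fold lower. B cells (29.2% and 21.1% against 10.4% and 10.9%) and NK cells (9.81% and 6.58% against 2.75% and 3.42%) also had lower shares in both pneumonia libraries. Monocytes were at 2.49% and 2.92% in sham, 1.37% in mild and 0.835% in severe, and ILC2 at 1.81% and 0.781% in sham, 0.202% in mild and 0.634% in severe. Dendritic cells (3.2% and 3.36%, against 4.01% and 4.19%) and plasma cells (2.23% and 3.55%, against 2.24% and 1.77%) differed less as shares of all annotated cells. Mast cells were 0 of 5371 cells in sham 1, for which the upper 95% limit is 0.0687%, and 0.384%, 0.5% and 0.0503% in sham 2, mild and severe. Shares sum to 100%, so the neutrophil share alone lowers the others. Among cells other than neutrophils, T cells stood at 0.933 (mild) and 0.633 (severe) times the sham mean, B cells at 0.667 and 0.864, NK cells at 0.544 and 0.836, monocytes at 0.824 and 0.619 and ILC2 at 0.253 and 0.98. Most of the lower T cell share in mild pneumonia was therefore the larger neutrophil share. On that denominator the Macrophage class stood at 5.57 and 7.69, dendritic cells at 1.98 and 2.56 and plasma cells at 1.26 and 1.23 times the sham mean. Mild and severe pneumonia had 1 library each, so no test of the shares was made, and the exact (Clopper-Pearson) intervals, like all intervals and floors here, cover counting error only.

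**Figure D3:**
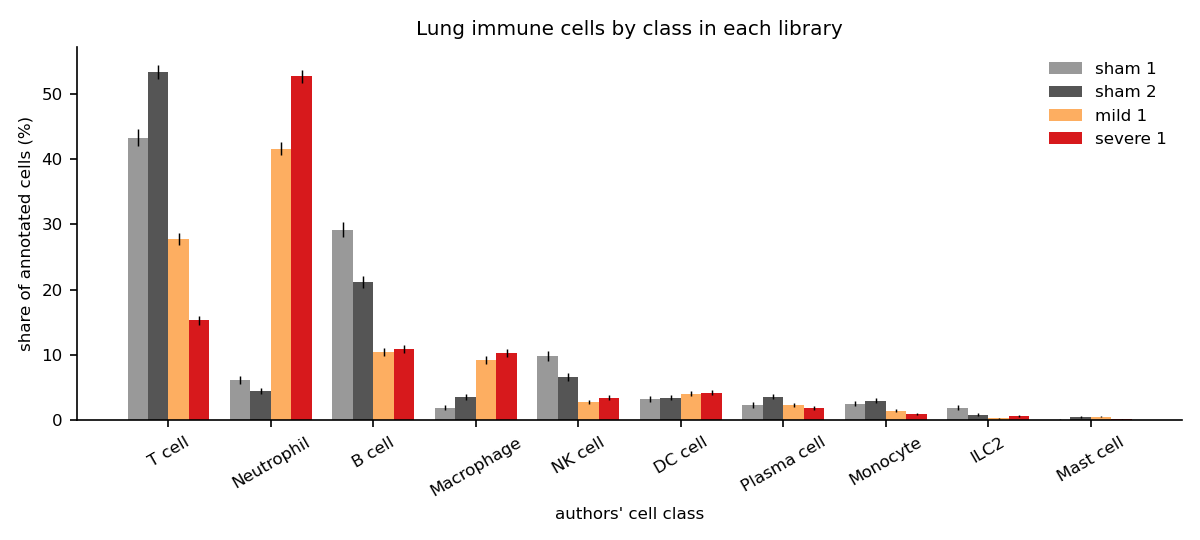
Share of annotated cells (percent, axis from 0) of each cell class in the 4 single-cell libraries; bars are libraries and lines are exact 95% intervals. Neutrophils stood at 6.05% and 4.41% in the sham libraries and at 41.6% and 52.7% in mild and severe pneumonia.

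Within the Macrophage class (100, 264, 953 and 1018 cells in sham 1, sham 2, mild and severe, median UMIs 12031.5, 13035, 14720 and 13893), inflammatory genes were far higher in both pneumonia libraries. Arg1, the arginine-degrading enzyme, was at 0 and 0.558 CPM (0 and 2 UMIs) in sham, 288 in mild and 714 in severe pneumonia, with no fold given because both sham values lie under the floor of 3 UMIs. Nos2, which uses the same substrate, was at 1.49 and 0.279 against 85.4 and 256 CPM. Acod1 was at 2.99 and 3.07 against 561 and 1140 CPM, and Cxcl1 at 5.97 and 2.23 against 744 and 575 CPM. Il1rn was at 5.97 and 8.94 against 323 and 535 CPM, Ccl3 at 38.1 and 32.7 against 467 and 855, Cxcl10 at 10.5 and 13.1 against 312 and 468, and Il10 at 5.23 and 3.07 against 65.0 and 92.1 CPM. Against the nearer sham library these folds were 124 (mild) and 96.3 (severe) for Cxcl1, 36.1 and 59.9 for Il1rn, 12.4 and 17.6 for Il10 and 4.43 and 9.41 for Tnf (28.4 and 22.1 against 126 and 267 CPM). AA467197, Cxcl3, Il1b (3.97 and 5.97), Cxcl2 (7.06 and 10.3) and Ccl2 (7.28 and 9.46) were higher in both libraries as well, and Il6 (1.49, 10.9, 57.6 and 130 CPM) passed the size rule in severe pneumonia only. Lower in both were Sell, the homing receptor L-selectin (343 and 213 against 33.3 and 30 CPM), Arhgef37 (11.5-fold and 9.57-fold lower), Nhsl2, Stxbp6 and Dgkg. Cx3cr1, the fractalkine receptor, was at 97.1 and 140 in sham, 62.3 in mild and 30.6 CPM in severe, 3.17-fold lower in severe. The adrenergic receptor gene Adrb2, at 45.5, 21.8, 25.2 and 33.8 CPM, and Crem, Dusp1, Nr4a1, Nr4a3, Mrc1, Isg15 and Adrb1 did not pass the size rule, and Ifnb1 and Il12b had no counts in either sham library.

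The cells behind this class differed between the libraries. Cells with a Ly6c2 or Ccr2 UMI (monocyte genes) and no C1q UMI made up 93.0% and 95.5% of the class in sham, 41.1% in mild and 45.5% in severe, while cells with a C1q UMI made up 6.0%, 4.55%, 47.1% and 41.6%. Summed classical monocyte markers were at 14600 and 12400 CPM in sham against 5220 and 6390, and summed interstitial macrophage markers at 1650 and 2020 against 7210 and 6150 CPM. Alveolar macrophage markers summed to 1570 and 1530 against 3200 and 3860 CPM, and neutrophil markers to 3660 and 1090 against 1390 and 2090 CPM. By gene, 6 and 5 of 9 interstitial macrophage markers were higher and 0 and 1 lower past the size rule in mild and severe (median log2 3.56 and 2.82), while 6 and 4 of 10 classical monocyte markers (-1.84 and -1.62) and 3 and 3 of 8 non-classical monocyte markers (-1.83 and -1.66) were lower. Alveolar macrophage markers had larger medians (3.79 and 3.63), with 2 and 3 of 9 higher and 0 lower. The rise was therefore not particular to interstitial macrophage markers. Markers of innate lymphoid cells summed to 43.3 and 33.2 CPM in sham against 520 and 901, which came mostly from Arg1 and Areg (8.21 and 15.4 against 202 and 159 CPM). Platelet markers summed to 15.7 and 2.23 against 186 and 162 CPM, which came mostly from Pf4 (14.2 and 1.12 against 181 and 158 CPM), a gene that is also on the interstitial macrophage list, while the platelet gene Ppbp stayed at 0.684 and 0.609 CPM in mild and severe. Areg, Pf4 and Ppbp were chosen after the sums were seen, and doublets were not removed.

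Cytokine and chemokine genes had the largest median log2 ratios of the fixed lists in this class. Of 28 measured, 16 were higher in mild and 19 in severe past the size rule and 0 lower in either (median log2 ratio 2.64 and 3.27, both at percentile 100 of 10000 random lists). NF-kB genes (14 and 22 of 30 higher, 0 lower, medians 1.33 and 1.54), NRF2 targets (15 and 17 of 27 higher, 1 lower; 1.35 and 1.62), anti-inflammatory genes (7 and 6 of 27 higher, 1 and 0 lower; 1.79 and 1.95) and glycolysis genes (7 and 9 of 27 higher, 0 lower; 0.66 and 0.92) stood at the same percentile in both libraries. Interstitial macrophage identity genes (10 and 8 of 28 higher, 2 lower; 1.42 and 1.49), immediate-early genes (11 and 10 of 29 higher, 1 lower; 1.13 and 1.01) and phagocytosis genes (7 and 5 of 24 higher, 3 lower; 0.58 and 0.42) were higher too, as were antigen presentation genes (6 and 7 of 29 higher, 0 lower; 0.41 and 0.45). Interferon-stimulated genes were not, with 2 and 3 of 28 higher, 2 and 1 lower, and medians of -0.36 (percentile 9.59) and -0.21 (percentile 55.3). The cAMP and CREB targets (3 and 3 of 29 higher, 0 and 2 lower; 0.10 and 0.13), adrenergic signalling (0 higher and 1 and 2 of 21 lower; -0.08 and -0.09), oxidative phosphorylation (0 of 30; 0.11 and 0.02), cholesterol and LXR (2 and 4 of 28 higher, 1 lower; -0.11 and -0.44), stress response (1 of 27 higher in each; 0.50 and 0.56), cell cycle (0 and 1 of 19 higher, 1 lower; 0.39 and 0.11) and inflammasome genes (2 and 4 of 28 higher, 2 lower; -0.34 and 0.02) had few members past the size rule. Genes within a list are not independent of each other, so these percentiles are descriptive.

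**Figure D4:**
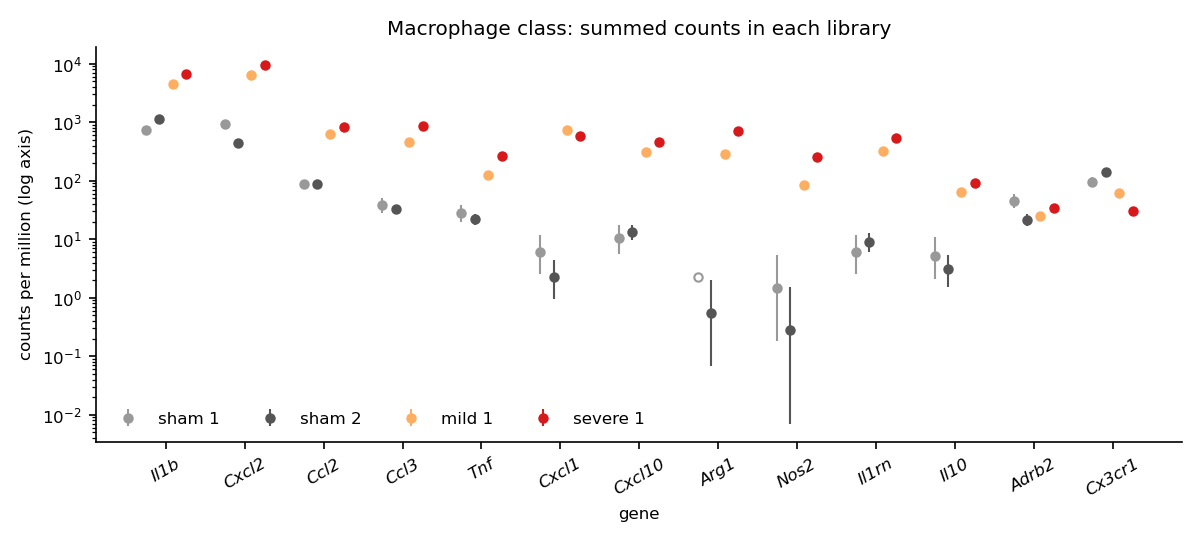
CPM (log axis) of 13 genes in the Macrophage class of the 4 single-cell libraries; points are libraries, lines are exact 95% Poisson intervals, and open symbols mark 0 counts at the library's floor. Arg1 stood at 0 and 0.558 CPM in the sham libraries and at 288 and 714 CPM in mild and severe pneumonia.

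The summed counts of this class could be fitted only with the 2 sham libraries as the measure of spread (1 residual degree of freedom). Each pneumonia library was assumed to vary as the sham libraries did, so these p-values hold no spread within mild or severe pneumonia and say nothing about other mice with either. Under that assumption edgeR called 343 of 12743 genes in mild against sham (287 higher, 56 lower) and 499 in severe against sham (404 higher, 95 lower), and the counts depended on the settings (847 to 2014 for mild and 939 to 2078 for severe). Il1rn (log2 5.50 in mild and 6.30 in severe, adjusted p = 0.0171 and 0.0133), Arg1, Nos2, Cxcl1, Cxcl10, Ccl3, Il10, Ccl2 and Tnf (2.52 and 3.67, adjusted p = 0.0302 and 0.0157) were among the genes called in both. Il1b, Cxcl2 and Il6 were called in severe (adjusted p = 0.0402, 0.0354 and 0.0467) but not in mild (0.0665, 0.0517 and 0.0936). Adrb2 was called in neither (adjusted p = 0.86 and 0.713). Severe against mild directly called 0 genes (198 at an unadjusted p under 0.05, with 2 called by DESeq2, 2 with other size factors and 34 without the low-count filter).

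Neutrophils (325, 333, 4333 and 5239 cells) carried more chemokine and acute-phase mRNA and less granule mRNA in pneumonia. S100a8 (162000 and 112000 CPM) and S100a9 (158000 and 132000 CPM) took a large part of the sham totals, so a total without 7 neutrophil markers and mitochondrial genes was also used. It made the rises of Ccl3 and Tnf smaller and the falls of Camp and S100a8 larger. All 51 single-cell gene ratios that it moved (of 393) were in neutrophils, and none changed direction. Ccl3 was at 18.9 and 7.77 CPM in sham, 3460 in mild and 6400 in severe, and the acute-phase gene Saa3 at 19.8 and 19.7 against 4000 and 8060 CPM. Tnf was at 27.3 and 29.3 against 515 and 1120 CPM, Cxcl10 at 3.1 and 4.57 against 475 and 706, Il1rn at 45.3 and 89.1 against 1300 and 2430, and Cxcl2 at 3030 and 2590 against 17000 and 24400 CPM. Gpnmb, Gstm1, Mreg, Gdf15 and Gbp5 were higher as well. The granule genes Camp (4560 and 7390 against 887 and 104 CPM), Ltf (2500 and 3500 against 499 and 58.7) and Ngp (11500 and 9170 against 2450 and 438) were 43.9-fold, 42.6-fold and 21.0-fold lower in severe pneumonia, and S100a8 and S100a9 were 3.91-fold and 3.3-fold lower. Ly6g (388 and 337 against 147 and 118 CPM) and Retnlg in severe (2.16-fold lower) were lower too. Il1b, at 2450 and 5890 in sham against 7750 and 8190 CPM, differed between the sham libraries by more than it differed from the nearer sham library. Of the fixed lists, NF-kB (20 and 20 of 28 higher, 0 lower, median log2 2.38 and 2.72), cytokines (11 and 10 of 24 higher; 2.73 and 3.62), NRF2 targets (12 and 14 of 28 higher, 3 lower; 1.56 and 2.18), antigen presentation (9 and 12 of 27 higher; 1.13 and 1.77), inflammasome (8 and 10 of 28 higher; 1.07 and 1.20) and interferon-stimulated genes (4 and 4 of 27 higher; 0.72 and 1.08) had the most members higher. Neutrophil markers as a list were lower (4 and 7 of 10; -1.19 and -1.36). Ranks among random lists are not given for the fixed lists here, so their medians are not shown to exceed those of other genes in the class.

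In T cells (2328, 4036, 2889 and 1517 cells), the heat-shock gene Hspa1a was at 25.6 and 88.6 CPM in sham, 920 in mild and 496 in severe, the decoy receptor Il1r2 at 9.95 and 10.7 against 68.8 and 52.2, and the cytotoxic granule gene Gzma at 664 and 774 against 117 and 242 CPM. Cx3cr1 was 4.09-fold and 3.99-fold lower in mild and severe, and Afap1l2 stood at 73.9 CPM in severe and under 2 CPM in the other libraries. NK cell markers of the T cell class summed to 1190 and 1890 CPM in sham against 850 and 999 CPM. Their median log2 was -0.09 in mild and -0.49 in severe, so no T cell effect was read from Gzma or Cx3cr1. B cells (1568, 1595, 1077 and 1078 cells) also had more Hspa1a (20.3 and 31.3 against 1450 and 734 CPM), Hspa1b and the co-chaperone Dnajb1 (37.6 and 49.2 against 511 and 292 CPM), and less mt-Nd3 (465 and 721 against 149 and 125 CPM). In NK cells mt-Nd3 was lower as well (287 and 433 against 108 and 93.4 CPM). Mitochondrial genes held 2.15% and 2.95% of all UMIs in sham against 1.52% and 1.32%, so no B cell effect was read from mt-Nd3. NK cells (527, 497, 286 and 340 cells) had Hspa1a at 16.3 and 55.8 against 732 and 347 CPM, the G-protein regulator Rgs16 at 16.1 and 11.6 against 151 and 68.6 CPM, and the T cell gene Themis 4.49-fold and 10.4-fold lower. T cell markers of the NK class were lower as well (median log2 -0.32 and -0.83, with Cd3e at 63.1 and 73.2 against 26.2 and 33.6 CPM), so no NK cell effect was read from Themis. Immediate-early and dissociation stress genes were the list with the most members past the size rule in each of these 3 classes (12 and 10 of 28 in T cells, 14 and 12 of 30 in B cells, 15 and 16 of 29 in NK cells, 0 lower). Cxcl2, Saa3 and Il1b counts were also higher in these lymphocytes, but a Cxcl2 UMI was found in 7.56% and 2.65% of sham T cells (median depth 6539 and 6118 UMIs) and in 36.4% and 57.0% of mild and severe T cells (6074 and 6247 UMIs). Whether this was background RNA or expression by lymphocytes was not tested, and no lymphocyte effect was read from these genes. The hemoglobin genes of T cells and neutrophils, named by rule as lowest, differed between the sham libraries (Hbb-bs 25.4 and 350 CPM in T cells), and no pneumonia effect was read from them.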

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

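All tests of explanations below were chosen after the results were seen, and those of scaling and of the sort gate replaced earlier tests whose values had been seen.

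Interferon-stimulated genes were lower in NE then LPS than in LPS libraries (31 of 32), and their interaction had a median log2 of -0.72. Scaling between libraries was argued against: 1 factor per library moves all genes alike, yet only 1.99% of 603 other genes of the same level (the 20 nearest in mean CPM to each member) lay at or below the list median. That share rests on the same values as the list call that flagged these genes, so it is not an independent test. A weaker LPS response of every kind was also argued against by the NF-kB list, whose median was 0.40 in the same comparison. The labels give the pretreated libraries 3 additional hours with stimuli and no time in culture before LPS for the others. A longer time in culture could produce the same pattern and cannot be separated from NE here. An equal effect of NE on these genes with and without LPS was argued against as the whole cause, since their interaction was called with an estimated correlation, as given above. Their median in NE against unstimulated libraries was -0.20, a call not held with that setting, so a smaller effect without LPS was left open. The interaction carries the same additional hours, so it does not show what NE itself did in cells given LPS.

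Inflammatory genes were higher in the Macrophage class of the pneumonia libraries. The tests used 11 always-reported genes that had already passed the size rule in both pneumonia libraries. They were Tnf, Il1b, Il10, Cxcl1, Cxcl2, Cxcl10, Ccl2, Ccl3, Nos2, Il1rn and Arg1. Over these genes, free neutrophil RNA could account for a median of at most 2.97% of the class level. The highest value was 18.5%, for Ccl3 in severe. That argued against it as the main cause for these genes. A change in the share of cells with a Ly6c2 or Ccr2 UMI and no C1q UMI was argued against as the whole cause. Within those cells the smaller of the mild and severe median folds over the same genes was 12.2, and the lowest fold of a gene was 4.5. Arg1 and Nos2 rested on few sham UMIs, so the size of their folds is uncertain. The mix of cells inside that subset can itself differ between libraries, so a different mix in general stays open. Background RNA from cells other than neutrophils and doublets were not tested.

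Cx3cr1 was near 0 and Itgax high in the sorted macrophages, whose gate required CX3CR1 and excluded CD11c. Conventional dendritic cells were argued against as the main source of Itgax: at the marker to Itgax ratios of the DC class in the sham libraries, none of their 10 markers allowed more than 2.62% of it. Those ratios are of fresh cells and of UMI counts, and ratios between genes need not carry over to the bulk assay. Alveolar macrophages stay open, since no class measures their ratios, and their median marker CPM (0.835% of that of Itgax) does not decide it. No biological explanation, such as a change of these transcripts in culture, was tested.

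Other differences between the groups' LPS responses, each an interaction on the log2 scale, were as follows. It was positive for 620 genes and negative for 506, where a positive value marks a larger rise, a smaller fall or a turn from fall to rise after NE, and a negative value the reverse. The list median was 0.24 for NF-kB genes, -0.08 for antigen presentation genes and 0.10 for immediate-early genes. Positive were those of Lif (2.61), Rhou (1.93), F3 (1.79), Dusp2 (1.61), Odc1 (1.59), Errfi1 (1.59), Adrb2 (1.56), Nol4l (1.51), Tnf (1.24), Nfkbia (1.07), Ier3 (1.03) and Il1rn (0.61). Negative were those of Ifit3b (-2.41), Thbs1 (-2.25), Rsad2 (-2), Nt5e (-1.84), Pde4b (-1.81), Cmpk2 (-1.81), Ets2 (-1.78), Lpar1 (-1.77), Cxcl3 (-1.66) and Nos2 (-1.40). So were those of Nr4a1 (-1.21), Cxcl2 (-1.07), Il1b (-0.96), Cd83 (-0.86), Cd80 (-0.71), Cd86 (-0.50) and Ccl3 (-0.32). No explanation of these was tested beyond those above.

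Barcodes without a class (470, 544, 559 and 469 in sham 1, sham 2, mild and severe) carried cell-type signal not used elsewhere. Their summed interstitial macrophage markers were at 391 and 943 CPM in the sham libraries, 2590 in mild and 2140 in severe. Platelet markers were at 7.16, 33.1, 46.8 and 142 CPM in the same order, and fibroblast or mural markers at 6.97, 7.72, 6.42 and 22.8 CPM.

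Regrouping the bulk libraries tested whether chance splits could give as many calls. With 10 splits per pair of groups, only the real one reached its count (1 of 10), which is too few for a share under 0.05: 6582 genes against at most 0 in another split for LPS with unstimulated, 4626 against 1 for NE with unstimulated, 5038 against 2 for NE then LPS with LPS, and 6327 against 1 for NE then LPS with NE. For the interaction, 1 of 100 groupings (the real one) reached 1126 genes, and the highest other reached 507.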

How the results depend on the processing

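The alternatives were chosen before the data were examined, except division of the counts by 4. Requiring an absolute log2 fold change of at least 1 left fewer genes by construction: 908 higher and 503 lower for LPS against unstimulated, 487 and 243 for NE against unstimulated, 514 and 271 for NE then LPS against LPS, 986 and 588 for NE then LPS against NE, and 71 and 78 for the interaction. No other bulk alternative moved a count of calls by over 1.5 times; genes higher after LPS ranged from 2977 to 3554, for example. Of 440 named bulk results, 415 were called, 27 of them lost the call under at least 1 alternative, and 0 turned direction. With an estimated correlation, lists called went from 10 to 8 (LPS), 6 to 1 (NE), 7 to 3 (NE then LPS against LPS), 9 to 4 (NE then LPS against NE) and 7 to 4 (interaction). With fry, which asks whether a list changed rather than whether it changed more than other genes, they went to 15, 14, 15, 14 and 10. Of the results that fry called, 4 had the opposite direction from camera, which called none of them: immediate-early genes (adjusted p = 2.87e-05) and inflammasome genes (6.87e-06) in NE against unstimulated, inflammasome genes in NE then LPS against LPS (7.47e-09), and phagocytosis genes in NE then LPS against NE (0.0081). Leaving neutrophils out of the denominator raised every other class's share by construction, to these multiples of the sham mean in mild and severe: B cells 0.667 and 0.864, dendritic cells 1.98 and 2.56, ILC2 0.253 and 0.98, Macrophage class 5.57 and 7.69, monocytes 0.824 and 0.619, NK cells 0.544 and 0.836, T cells 0.933 and 0.633, mast cells 4.27 and 0.53, and plasma cells 1.26 and 1.23, a turn from 0.775 and 0.613. Leaving out 1 sham library gave, lowest to highest, 0.355 to 0.49 and 0.372 to 0.514 for B cells, 0.112 to 0.258 and 0.351 to 0.812 for ILC2, 2.62 to 4.92 and 2.93 to 5.5 for the Macrophage class, 0.28 to 0.418 and 0.349 to 0.52 for NK cells, and 6.88 to 9.45 and 8.71 to 12 for neutrophils. It gave 0.52 to 0.641 and 0.286 to 0.352 for T cells, 0.631 to 1.0 and 0.499 to 0.793 for plasma cells and 1.3 and 0.131 for mast cells (from 2.6 and 0.262), which reflects the difference between the sham libraries. In the class sums, calls in mild against sham went from 343 to 1436 (RLE), 847 (DESeq2) and 2014 (no filter), in severe against sham from 499 to 1515, 939 and 2078, and in severe against mild from 0 to 2, 2 and 34; the cause was not tested. Of 393 single-cell gene values, 186 moved when sham 1 was left out and 186 when sham 2 was, 51 (all in neutrophils) with the total that leaves out neutrophil markers and mitochondrial genes, and 0 with cells of at least 1000 UMIs. With 1 sham library left out, no residual degree of freedom remained and no test was made.

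The labels give the same replicate numbers in each bulk group but do not say that a number marks a shared mouse or day. With a replicate block the calls were 3288 higher and 3044 lower for LPS against unstimulated, 2353 and 2587 for NE against unstimulated, 2537 and 2460 for NE then LPS against LPS, 3530 and 3199 for NE then LPS against NE, and 646 and 512 for the interaction. Of the list results, 2 gained a call with the block and 0 lost one. Deviations of the 18 same-number pairs correlated at -0.027 to 0.039, those of different numbers at -0.037 to 0.033, and 6 of 12 libraries matched their own number best.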

Other observations

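The observations below were chosen after the results were seen, and none of them was tested further.

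In these macrophages Il10 stood at 26.3 CPM with NE then LPS, against 0.402 with LPS and 0 counts with NE. Against LPS alone, NE then LPS had higher Il1b, Il6, Cxcl1 and Csf3 and lower Ccl3, Ccl2, Cxcl10 and interferon-stimulated genes, so inflammatory genes moved in both directions. Part of this was seen with NE alone (Il1b and Cxcl1 higher, Ccl2 and Ccl3 lower), and no interaction was called for Il6, Cxcl1, Cxcl10 or Ccl2. Cells known to have had 3 hours in medium before LPS would separate the transmitter from time.

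The beta-2 receptor gene Adrb2 was 3.49-fold lower after LPS and 1.49-fold lower after NE, and among classes with at least 50 cells in every library it was highest in neutrophils (97.3 and 70.4 CPM) and monocytes (80.1 and 42.5 CPM) of the sham single-cell libraries. In the Macrophage class it stood at 45.5 and 21.8 CPM in the same libraries.

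Mki67 rose from 63.2 to 244 CPM after LPS while the other proliferation genes Top2a (54.4 and 48.7 CPM) and Pcna (169 and 155 CPM) did not rise with it.

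Hspa1a and Hspa1b were higher in T, B and NK cells of both pneumonia libraries and higher in mild than in severe, with Hspa1a in B cells at 20.3 and 31.3 CPM in sham, 1450 in mild and 734 in severe. Handling of the cells and the disease were not separated by the design.

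Scgb1a1, a club cell gene, stood at 241 CPM in severe neutrophils and at 0.31, 0.457 and 4.69 CPM in sham 1, sham 2 and mild, and a UMI of it was found in 2.54% of severe neutrophils, 12.7% of dendritic cells, 7.66% of the Macrophage class and 2.44% of T cells in severe pneumonia. S100a8 UMIs were found in 58.2% and 23.3% of T cells in sham and in 62.1% and 58.8% in mild and severe.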
